A study of Mus musculus with 12 samples.

How the data were processed

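The series holds ATAC-seq of MA1L cells, a mouse liver cancer line that lacks p53 and overexpresses Myc. ATAC-seq counts the cuts that a transposase makes in open chromatin. Cells carried either an empty vector or a guide RNA against Kmt2d (sgKmt2d), a gene for a histone H3 lysine methyltransferase that acts at enhancers. Each was given interferon gamma (IFNG) at 10 ng/ml or DMSO for 24 h. There were 3 libraries in each of the 4 groups, 12 in all, each from 50000 cells. Libraries are named here by group and replicate. The groups came from the sample labels, and each count column was matched to its library by its own peak list, which was the best match for 12 of 12 columns. Whether the replicates came from separate transductions is not given in the sources used here, so the vector and sgKmt2d cells are compared as 2 cell populations.

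The deposited count table holds whole-number read counts for 78318 regions and 12 libraries, with a lowest value of 1, so that 0 and 1 cannot be separated in it. Its regions had a median width of 670 bp, and every start occurred in at least 1 of the peak lists per library. In the deposited peak lists, each peak has a fold enrichment over its local background, a ratio computed by MACS2. The deposited peak lists also give the −log10 p and the −log10 q of each peak. The submitters' processing notes name Bowtie2 2.2.9 for alignment to the mm10 build, MACS2 for peak calling, and DiffBind and DESeq2. The settings of these tools and their filters are not given in the sources used here.

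Depth was read from the count table. Total counts ran from 19863811 (sgKmt2d_IFNG 3) to 44060311 (vector_IFNG 2), and the median count per region from 97 to 180. Between 13.5% and 22.4% of each library's counts lay in 10 regions, and between 10.0% and 16.5% in 2 of them. Each pair of replicates differed by more than counting error, with a chi-square per degree of freedom of at least 3.14, so no library was a copy of another.

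Counts were analysed in R 4.3.3 with edgeR 4.0.16. Regions were kept by filterByExpr with a minimum count of 10, which left 77885 and removed 433. Libraries were scaled by TMM, with factors from 0.956 to 1.07. A quasi-likelihood negative binomial model with the 4 groups was fitted to all 12 libraries (common dispersion 0.0237). Fold changes are on the log2 scale, and the error after each is its standard error (SE) from that fit with 3 libraries per group. P-values were adjusted by Benjamini-Hochberg, and a peak was called at an adjusted p below 0.05. The 5 contrasts were IFNG against DMSO in vector cells, the same in sgKmt2d cells, sgKmt2d against vector without IFNG, the same with IFNG, and the interaction, which is the IFNG effect in sgKmt2d cells minus that in vector cells. All tests were two-sided. The p-values measure the spread between replicates, which may be technical.

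The procedure was tested on simulated data in which 66 or 67 peaks were changed at each of 3 folds. In the 4 contrasts of 2 groups, a change of 4-fold was recovered in 92.4% to 98.5% of peaks, one of 2-fold in 53.7% to 65.7%, and one of 1.5-fold in 17.9% to 29.9%. For the interaction these shares were 78.8%, 32.8% and 4.48%. Between 5.56% and 10.5% of the calls were false. All other peaks were unchanged in the simulated contrast. Where far more peaks change, the adjusted threshold is less strict, so recovery may be higher than these shares.

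Peaks were assigned to genes with a GRCm38 (mm10) gene table of 21900 protein-coding genes. A peak inside a gene body took that gene, and any other took the nearest gene within 50 kb. This placed 65337 peaks (83.4%). The table has no strand, so transcription starts and ends could not be separated. Peaks within 1 kb of either end of a gene were classed as gene-end (15.5%), the others inside a gene as gene body (41.0%), and the rest as intergenic (43.5%). The share of gene-end peaks among called peaks was compared with that among peaks not called by Fisher's exact test, adjusted over 8 tests. Coordinates are counted from 1.

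There were 16 gene lists with 293 genes, none in more than 1 list. Of these, 290 were in the gene table and 256 had a peak. The lists were MHC class I antigen presentation, MHC class II antigen presentation, the interferon-gamma response core, checkpoint ligands and chemokines, interferon receptor and JAK genes, KMT2 complex and related chromatin regulators, DNA damage and repair, p53 targets, hepatocyte identity, cholangiocyte and progenitor, mesenchymal and fibroblast, endothelial, macrophage and Kupffer, lymphocyte, MYC targets and cell cycle, and housekeeping. Each list was tested with fry of limma 3.58.1, which asks whether a list's peaks move to one side on balance, and with camera at a preset correlation of 0.01 and at an estimated correlation. These p-values were adjusted over the 16 lists of a contrast. Peaks of a list that passed the threshold over all peaks are counted beside those that passed when adjusted over the list alone.

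Peaks were named by a rule. It took, for each contrast, the called peaks whose 3 libraries of one group all lay above the 3 of the other and whose level was at or above the median, and kept the 10 largest changes in each direction with 1 peak per gene. It added the 4 peaks of each list with the smallest p and the peaks of Kmt2d. Some of the peaks it named are not reported here. The contrasts, tests, gene lists, naming rule and most alternatives were fixed before the data were examined.

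Peaks called per library were compared by exact permutation tests of 3 libraries against 3, which cannot give a p below 0.1, and by exact permutation within strata over all 12. A region was taken as shared when at least 2 of the 3 libraries of each group had it. Alternatives were DESeq2 size factors, library totals, no filter, a filter at the median level, the DESeq2 1.42.0 Wald test, limma-voom, a fit to the groups of the contrast alone, the replicate number as a block, offsets from medians in 10 Mb windows, autosomes alone, a fold limit of 1 on the log2 scale, stricter q limits for peak lists, and leaving out each library. Further settings were chosen after seeing the data. These were leaving out the 10 highest peaks, offsets from a trend on the mean level, leaving out both vector_IFNG 2 (lowest correlations within its group) and sgKmt2d_IFNG 3 (lowest depth), gene lists restricted to gene-end peaks, and a 5 kb gene-end window. Other steps used Python 3.11.15 and bedtools 2.31.1.

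No genome sequence was used here, so the planned GC correction and motif search were not run. The planned classing of peaks by promoter, exon and intron was not run, since the gene table has no strand, transcription starts or exons. The nearest gene body replaced the nearest transcription start in the assignment of peaks. Sequencing reads and transcript levels were not analysed here.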

Results

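Chromatin accessibility was measured by ATAC-seq in MA1L mouse liver cancer cells that carried an empty vector or a guide against Kmt2d. Both populations were given IFNG, a cytokine that signals through JAK kinases, or DMSO for 24 h. Each of the 4 groups had 3 libraries. Total counts per library lay between 30636488 and 32037485 in vector_DMSO, 32825530 and 44060311 in vector_IFNG, 29240406 and 36417608 in sgKmt2d_DMSO, and 19863811 and 34938430 in sgKmt2d_IFNG.

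The libraries separated by transduction and by treatment. A principal component analysis was run on the 5000 peaks that varied most across the 12 libraries. Its first component held 62.5% of the variance of these peaks and set every vector library apart from every sgKmt2d library. The second held 15.3% and set every IFNG library apart from every DMSO library. Library vector_IFNG 2 stood somewhat apart, with a mean correlation of 0.963 with the other libraries of its group, which correlated at 0.982 with each other. It was also the deepest library, and sgKmt2d_IFNG 3 was the shallowest. Counts of changed peaks are therefore also given without both of these doubted libraries.

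Kmt2d itself, the targeted gene, had 1 peak, in its gene body on chromosome 15 (98870972 to 98872784). Its accessibility was similar in all groups. The log2 fold change was −0.12 ± 0.13 for sgKmt2d against vector without IFNG (adjusted p 0.514) and −0.06 ± 0.13 with IFNG (adjusted p 0.765). For IFNG it was 0.14 ± 0.13 in vector cells and 0.20 ± 0.13 in sgKmt2d cells. Accessibility at this gene does not check whether the guide edited it.

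The first question was which regions respond to IFNG in cells with an empty vector. The largest rise was at Ifi47, an interferon-inducible GTPase, where the peak on chromosome 11 (49081261 to 49081969) rose 27.4-fold (log2 4.78 ± 0.21, n = 3 libraries per group, edgeR adjusted p 5.54e-13). Peaks at other GTPase genes of the same family rose with it, among them a peak 2078 bp from Tgtp1 (4.09 ± 0.20) and Gm12250 (3.65 ± 0.25). A peak 8317 bp from Ubd, which encodes a ubiquitin-like modifier, rose by 3.53 ± 0.29. A peak assigned to Prm1 on chromosome 16 (10814265 to 10815437) rose by 3.73 ± 0.17 and lay 29315 bp from Socs1, an inhibitor of JAK signalling. The falls named were smaller. They included peaks in Pcdh9, a protocadherin (−1.34 ± 0.22), in Enox1 (−1.21 ± 0.18) and 15027 bp from Cdh2, which encodes N-cadherin (−1.19 ± 0.18). The lowest named peak, on chromosome 10 (16600692 to 16601526), had no gene within 50 kb and fell by 2.01 ± 0.25. By the rule that named the peaks of this paragraph, the 3 libraries of one group all lay above the 3 of the other.

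Among the gene lists in vector cells, the interferon-gamma response core rose most broadly. Of its 156 peaks, 87 rose and 1 fell, and 37 of its 39 genes with a peak had at least 1 that rose (100 and 2 when adjusted over the list alone). Zbp1, a sensor of nucleic acids, rose by 3.16 ± 0.10 and Irgm1 by 3.02 ± 0.13. For MHC class I antigen presentation, 15 of 35 peaks rose and 1 fell (18 and 1 adjusted over the list alone). Nlrc5, the transactivator of MHC class I genes, rose by 2.51 ± 0.13 at its gene end, Psmb8, a subunit of the immunoproteasome, by 1.84 ± 0.20, and Tap1, a peptide transporter, by 0.86 ± 0.11. For MHC class II antigen presentation, 8 of 22 peaks rose and none fell (13 and 1 adjusted over the list alone), led by Ciita, the transactivator of MHC class II genes (3.10 ± 0.24). For checkpoint ligands and chemokines, 8 of 46 peaks rose and none fell (14 and 0 adjusted over the list alone). They included Tnfrsf14, the ligand of BTLA (2.49 ± 0.14), Cd274, which encodes PD-L1 (1.37 ± 0.13), Ido1, a tryptophan-degrading enzyme (2.22 ± 0.33), and a peak 1573 bp from the chemokine gene Ccl2 (1.15 ± 0.16). By fry the adjusted p was 6.63e-10 for the core, 0.000291 for MHC class I, 6.80e-06 for MHC class II and 0.000398 for the checkpoint list. With an estimated correlation the adjusted p was 9.79e-09, 0.0116, 0.000697 and 0.0153.

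The other 12 lists did not pass fry in vector cells, with adjusted p from 0.069 to 0.931. Of the interferon receptor and JAK peaks, 6 of 59 rose and none fell (7 and 0 adjusted over the list alone), among them a peak 9663 bp from Ifnar2, a receptor subunit (0.74 ± 0.12). In the KMT2 list 1 of 57 rose and 3 fell, at Arid1a (0.53 ± 0.15), Ezh2 (−0.69 ± 0.16 and −0.87 ± 0.22) and Crebbp (−0.60 ± 0.17), and the counts were the same when adjusted over the list alone. In DNA damage and repair 1 of 65 rose, at Apobec3, a cytidine deaminase (0.86 ± 0.14), and 1 fell (1 and 0 adjusted over the list alone). Of the p53 targets, 3 of 60 rose and 1 fell, with the same counts adjusted over the list alone. The MYC and cell cycle list had 2 of 79 up, led by a peak 16644 bp from the cyclin gene Ccne1 (2.29 ± 0.22), and 1 down, 42808 bp from Odc1, an enzyme of polyamine synthesis (−1.41 ± 0.27), with the same counts adjusted over the list alone. Counts of risen and fallen peaks were 0 and 0 of 36 for hepatocyte identity, 1 and 1 of 46 for the cholangiocyte list, 1 and 3 of 108 for the mesenchymal list and 2 and 1 of 61 for the endothelial list. They were 0 and 0 of 29 for macrophages, 2 and 1 of 11 for lymphocytes and 1 and 0 of 53 for housekeeping. Adjusted over the list alone, these 7 lists had 0 and 0, 2 and 1, 0 and 1, 4 and 1, 0 and 0, 2 and 1, and 0 and 0. The lymphocyte rises were in Il2rb, a receptor subunit gene (4.6-fold), and 48170 bp from Gzmb, which encodes a granzyme (3.51-fold).

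In total, edgeR called 4253 of 77885 peaks for IFNG in vector cells, 2641 higher and 1612 lower, and 1596 of them changed by at least 1 on the log2 scale (1316 higher and 280 lower). Without vector_IFNG 2 and sgKmt2d_IFNG 3 the call was 3001 higher and 1355 lower. The total was 6857 without vector_IFNG 3, 2543, 2289 and 2370 without vector_DMSO 1, 2 and 3, 2480 in a fit to these 6 libraries alone and 2732 with a filter at the median level. Groups did not overlap at 23.6% of peaks, where chance gives 10%.

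In sgKmt2d cells, IFNG raised peaks at many of the genes named for vector cells. The Ifi47 peak rose 20.9-fold (log2 4.38 ± 0.19, adjusted p 6.93e-13), the Prm1 peak near Socs1 by 3.88 ± 0.17, the peak 2078 bp from Tgtp1 by 3.81 ± 0.19 and Ubd by 3.50 ± 0.26. A second Tgtp1 peak, at the gene end, rose by 3.89 ± 0.17, and by 3.89 ± 0.18 in vector cells. Tgtp2 and Dtx3l, 2 further interferon-induced genes, rose by 3.56 ± 0.19 and 3.44 ± 0.24. Falls included Rap1gds1 (−1.60 ± 0.22), Cbfa2t3, a transcriptional corepressor (−1.13 ± 0.18), and Lep, the leptin gene (−1.07 ± 0.16).

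The same 4 lists rose in sgKmt2d cells. In the interferon-gamma response core 82 of 156 peaks rose and none fell, at 36 genes (96 and 2 adjusted over the list alone), with Zbp1 at 2.76 ± 0.10 and Irgm1 at 3.24 ± 0.13. In MHC class I, 10 rose and none fell (19 and 2 adjusted over the list alone), with Nlrc5 at 2.48 ± 0.13, Psmb8 at 1.39 ± 0.19 and Tap1 at 0.97 ± 0.11. In MHC class II, 5 rose and none fell (8 and 0 adjusted over the list alone), with Ciita at 2.81 ± 0.23. Checkpoint ligands and chemokines had 7 up and none down (10 and 0 adjusted over the list alone), with Tnfrsf14 at 2.15 ± 0.13, Cd274 at 1.31 ± 0.13 and Ido1 at 1.93 ± 0.34. The adjusted p of fry was 1.19e-09, 0.000327, 6.16e-06 and 0.00135 in that order. With an estimated correlation the adjusted p was 1.89e-08, 0.00822, 0.000415 and 0.0222.

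None of the other lists passed in sgKmt2d cells (adjusted p 0.0548 to 0.918). Interferon receptor and JAK genes had 1 peak up, 29406 bp from Jak2 (1.47 ± 0.28), and none down. The KMT2 and hepatocyte lists had none up or down, and DNA damage and repair had 1 up, again Apobec3 (0.99 ± 0.14). The MYC and cell cycle list had 4 up, at Ccne1 (1.14 ± 0.20) and at 3 peaks near Ccnd1, a cyclin gene (0.91 ± 0.15, 0.50 ± 0.13 and 0.51 ± 0.14), and none down. Risen and fallen peaks were 0 and 1 for p53 targets (Btg2, −0.66 ± 0.16), 1 and 0 for the cholangiocyte list, and 1 and 1 for the mesenchymal list (Fn1, 2.46-fold, and Cdh2, log2 −0.81 ± 0.18). They were 3 and 0 for the endothelial list (Flt1, Emcn and Kdr, 0.61 to 0.98), and 1 and 0 for each of the macrophage (Csf1r, 0.54 ± 0.13), lymphocyte (Gzmb, 2.62 ± 0.32) and housekeeping lists (Ywhaz, 0.46 ± 0.10). Adjusted over the list alone, the macrophage and lymphocyte lists had 2 up each, and the other 10 of these lists had the counts given.

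**Figure D1:**
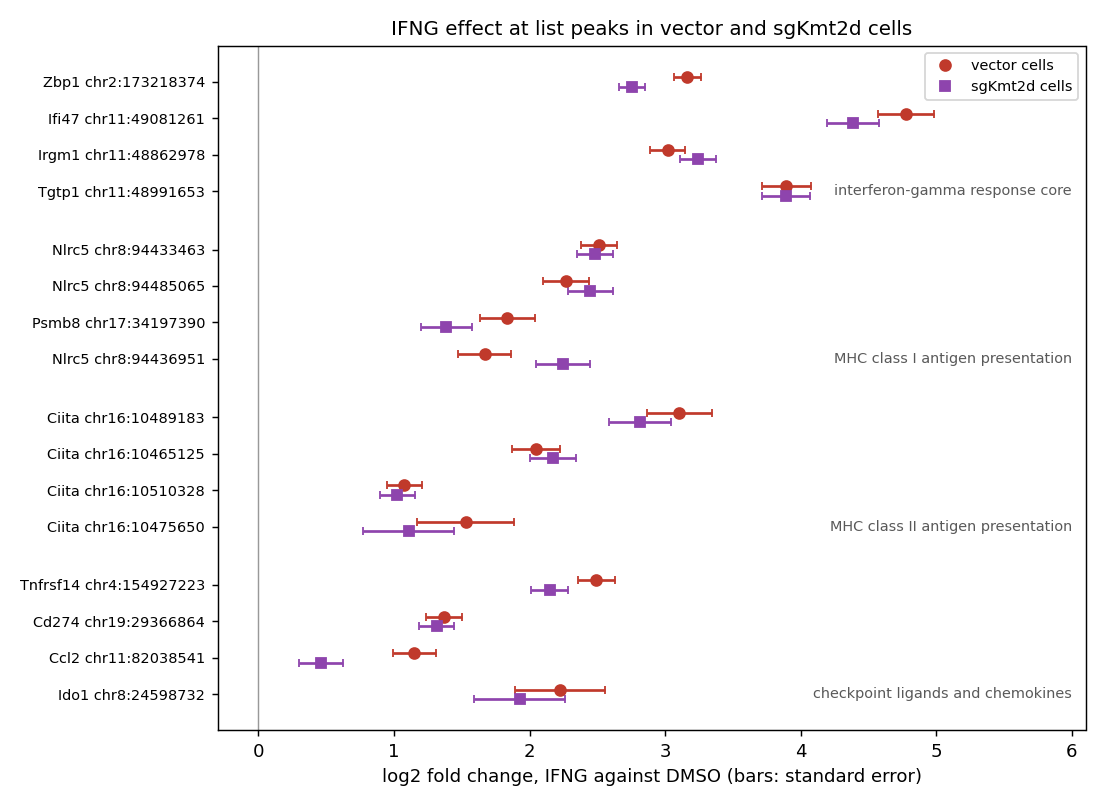
Log2 fold change of accessibility with IFNG against DMSO (x axis) at 16 peaks of 4 gene lists (y axis), in vector cells (circles) and sgKmt2d cells (squares); bars are 1 SE, with 3 libraries per group. The peaks are the 4 of each list with the smallest p for IFNG in vector cells, so they do not stand for their lists. A clear change in vector cells was fixed by that choice. Every peak shown lies above 0 in both populations, and Ifi47 is the highest at 4.78 in vector and 4.38 in sgKmt2d cells.

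In total, 2815 peaks were called for IFNG in sgKmt2d cells, 2319 higher and 496 lower, of which 1246 changed by at least 1 on the log2 scale (1141 higher and 105 lower). Without vector_IFNG 2 and sgKmt2d_IFNG 3 the call was 3269 higher and 1534 lower. Without vector_IFNG 2 alone, which is in neither group of this contrast but enters the shared fit, it was 3659 higher and 1284 lower. The filter, the scaling and the estimate of spread all change when it is left out. The total was 1731, 1838 and 1844 without sgKmt2d_DMSO 1, sgKmt2d_DMSO 2 and sgKmt2d_IFNG 2, and 1663 with a filter at the median level. The share of calls that rose was 82.4%, and 92.3% when libraries were scaled by their totals alone. Groups did not overlap at 20.9% of peaks, where chance gives 10%.

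A further question was whether the guide altered the response to IFNG. The difference in the IFNG effect, sgKmt2d minus vector, was −0.03 ± 0.19 at Nlrc5, −0.29 ± 0.33 at Ciita, −0.06 ± 0.19 at Cd274 and −0.40 ± 0.30 at the Ifi47 peak named above. It was larger at other peaks of the response core, 1.16 ± 0.24 near Gbp4 and −1.16 ± 0.28 at another Ifi47 peak. None passed the threshold over all peaks. The 1389 peaks that rose in both populations compare with 78.6 by chance, the 153 that fell in both compare with 10.3, and 1 peak was called in opposite directions. These chance counts take the calls as independent, although the same fit gave both with a shared estimate of spread. Peaks that rose in vector cells had a median of 1.00 there and 0.73 in sgKmt2d cells, and those that rose in sgKmt2d cells had 0.99 there and 0.79 in vector cells. Peaks that fell in vector cells had a median of −0.70 there and −0.29 in sgKmt2d cells. Those that fell in sgKmt2d cells had −0.75 there and −0.44 in vector cells. Each set shrank in the population in which it was not chosen. Across peaks, which are not independent replicates, the effects correlated with r = 0.521 and rho = 0.370, with r = 0.282 among peaks called in neither population.

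The interaction test in edgeR called 0 peaks, with 5942 at an unadjusted p below 0.05 where 3894 would be expected by chance and a smallest adjusted p of 0.132. That was at a peak assigned to Taf1b, a subunit gene of the RNA polymerase I initiation factor, named after its value was seen, where IFNG gave 0.36 in vector cells and 1.21 in sgKmt2d cells. By limma-voom 0 were called and by the DESeq2 Wald test 106 (77 higher and 29 lower). Without vector_IFNG 2 there were 11, 8 higher and 3 lower. All 11 are named here after their values were seen. The higher ones were assigned to Zfp704 (2.74), Arf6 (1.83), Tnfsf9 (1.40), Car6 (1.22), Pitrm1 (1.00), Taf1b (0.84), Tspan9 (0.77) and Cemip2 (0.68). The lower ones were at Cebpb, a bZIP transcription factor gene (−1.26), in Myo3a (−0.57) and on chromosome 5 (−0.62). Of these, the Myo3a and chromosome 5 peaks were among the 10 highest peaks, which held a large share of the counts. Without both doubted libraries there were 84 (45 higher and 39 lower). None of the 16 lists, the 4 interferon lists included, passed fry (adjusted p 0.69 to 0.956). Adjusted over the list alone, 3 core peaks were higher and 5 lower, the MYC and cell cycle list had 1 higher and 2 lower, and the other 14 lists had none. In simulated data a 2-fold difference of this kind was recovered at 32.8% of peaks, so smaller differences were mostly not detectable at this depth and number of libraries.

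**Figure D2:**
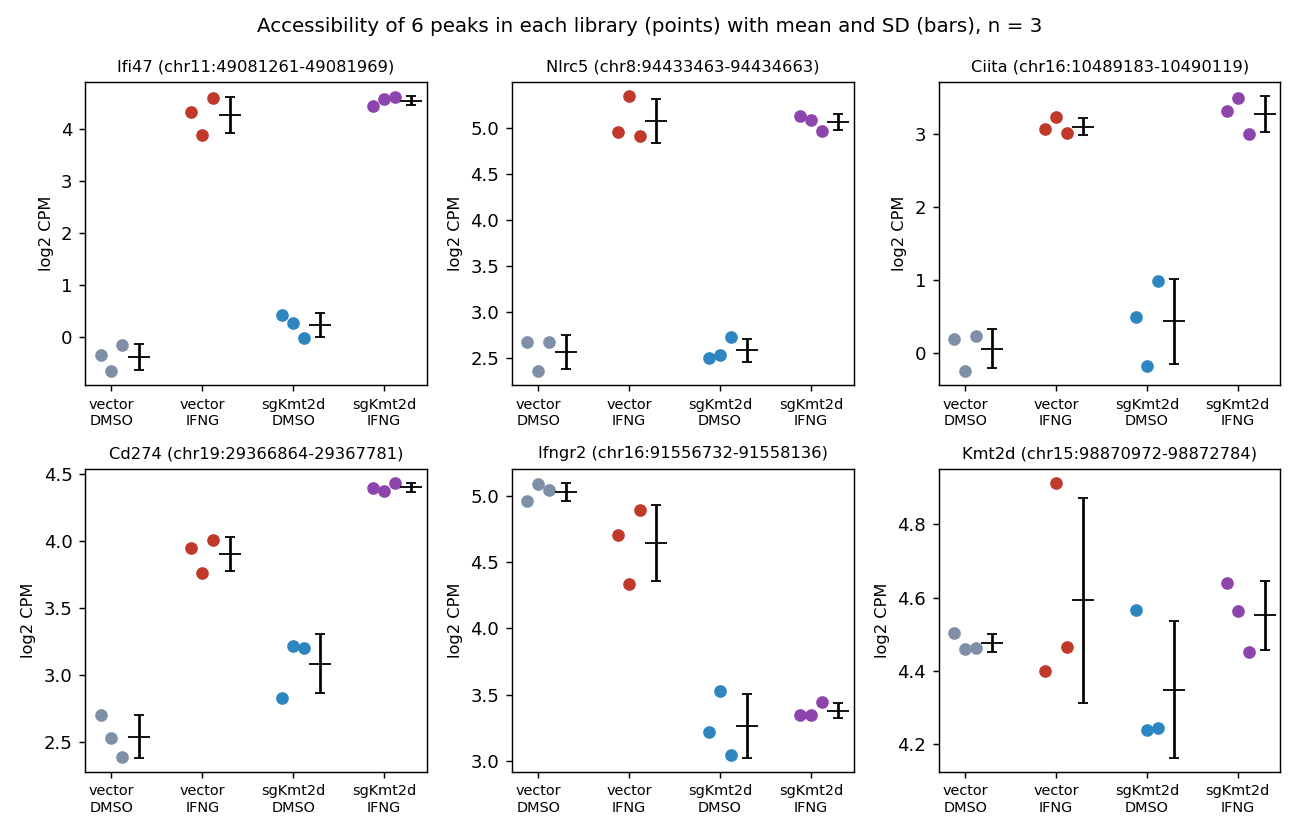
Accessibility as log2 CPM, normalised read counts scaled to a common library size (y axis), at 6 peaks in the 4 groups (x axis); points are libraries, and bars are the mean and SD of 3 libraries. Ifi47, Nlrc5, Ciita and Cd274 lie higher with IFNG in both populations, Ifngr2 lies lower in sgKmt2d cells by 1.76 without IFNG and 1.28 with it, and the Kmt2d peak is similar in all groups.

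The next comparison asked which regions differ between sgKmt2d and vector cells without IFNG. The named changes were large and went in both directions. A peak 3395 bp from Rp1, a photoreceptor gene, was 29.9-fold higher in sgKmt2d cells (log2 4.90 ± 0.26, adjusted p 9.81e-12). Peaks at Dmrta2, a transcription factor of the DMRT family (4.35 ± 0.14), in Oprm1, an opioid receptor gene (3.81 ± 0.22), and in Kcnd2, a potassium channel gene (13.9-fold), were also higher. The peak at Lrrk2, a large kinase, on chromosome 15 (91672698 to 91673670) was lower by −3.15 ± 0.17, and one 33131 bp from Naa11, an acetyltransferase gene, by −2.97 ± 0.17.

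Without IFNG, none of the interferon lists passed with an estimated correlation. Of the interferon receptor and JAK peaks, 5 were higher and 12 lower (the same adjusted over the list alone). They included Ifngr2, a subunit of the IFNG receptor, at −1.76 ± 0.14 (chromosome 16, 91556732 to 91558136, adjusted p 2.06e-09) and a peak of Jak1, the kinase that pairs with the other subunit, at 0.407-fold. The fry adjusted p was 0.0138, against an adjusted p of 0.845 with an estimated correlation, and it was 0.0594 without vector_DMSO 1, 0.0584 without sgKmt2d_DMSO 1 and 0.722 with the opposite direction at gene-end peaks alone. Checkpoint ligands and chemokines had 5 peaks higher and 17 lower (6 and 19 adjusted over the list alone), with a peak 20212 bp from Ccl2 at −1.46 ± 0.17, one 10941 bp from Cd47, the ligand of SIRPα, at −1.20 ± 0.17 and one 33205 bp from the adhesion gene Vcam1 at 1.46 ± 0.22 (fry adjusted p 0.00129, 0.413 with an estimated correlation). The lower checkpoint peaks lay at 5 of the 13 genes with a peak, and the higher ones at 3. Jak1 and Cd47 each also had 1 peak called higher. Cd274 was higher by 0.55 ± 0.14, on chromosome 19, where the median of all peaks was 0.33. In the response core 31 peaks were higher and 12 lower (29 and 12 adjusted over the list alone), with an Ifi47 peak (chromosome 11, 49087986 to 49088915) at 1.40 ± 0.17, Gbp7 at 1.13 ± 0.17 and a peak near Xaf1 at −0.96 ± 0.14 (fry adjusted p 0.000669, 0.413 with an estimated correlation). MHC class I had 10 higher and 1 lower (the same adjusted over the list alone), led by Psmb8 at 1.20 ± 0.21. Its fry adjusted p of 0.0461 became 0.949 with an estimated correlation and lay between 0.0594 and 0.166 without any library but sgKmt2d_DMSO 1. MHC class II had 3 higher and none lower (2 and 0 adjusted over the list alone), all between 0.46 and 0.84 at H2-DMa, Ciita and H2-Ab1 (fry adjusted p 0.0101, 0.853 with an estimated correlation).

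Peaks at markers of liver and other cell types lay on both sides. In the hepatocyte list 8 peaks were higher and 6 lower, with the same counts adjusted over the list alone. A peak 21445 bp from Foxa1, a pioneer factor of liver, was higher by 2.10 ± 0.24 and one in Gpc3, an oncofetal glypican, by 2.70 ± 0.41 (fry adjusted p 0.000669, 0.853 with an estimated correlation). Around Sox9, a transcription factor of biliary progenitors, one peak at 13235 bp was lower (−1.16 ± 0.14) and another at 49619 bp higher (1.52 ± 0.27), and the cholangiocyte list had 6 higher and 8 lower. In the MYC and cell cycle list 15 were higher and 7 lower, with both named peaks at Ccnd2, a D-type cyclin, at 1.22 ± 0.11 and 1.10 ± 0.12. Its fry adjusted p of 0.0138 became 0.949 with an estimated correlation, and lay between 0.0594 and 0.0753 without vector_DMSO 1, sgKmt2d_IFNG 1, 2 or 3. The p53 targets had 6 higher and 6 lower (5 and 5 adjusted over the list alone), among them a peak of Pmaip1, which encodes NOXA (0.98 ± 0.17). Their fry adjusted p of 0.0405 for higher became 0.949 with an estimated correlation, and lay between 0.0643 and 0.721 on leaving out any of 10 libraries. The cells lack p53.

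For the remaining lists without IFNG, fry did not pass (adjusted p 0.239 to 0.929). Higher and lower peaks were 5 and 7 for the KMT2 list (5 and 5 adjusted over the list alone), with one near Kdm5a, a histone demethylase gene, at −1.06 ± 0.14. They were 4 and 10 for DNA damage and repair (3 and 6), with Prkdc, a kinase of DNA end joining, at 1.69 ± 0.20 and a peak near Lig4, a ligase gene of the same pathway, at −1.71 ± 0.28. The mesenchymal list had 17 and 20 (18 and 20), with peaks in Cdh2 at 2.16 ± 0.27 and −0.80 ± 0.11. The endothelial list had 12 and 14, with a peak 11360 bp from Kdr, a VEGF receptor gene, at −1.14 ± 0.12 and one 47759 bp from Emcn at 1.58 ± 0.17. Macrophage, lymphocyte and housekeeping lists had 3 and 4, 2 and 2, and 2 and 4 (0 and 4), the last with a peak 4946 bp from Actb at −1.51 ± 0.17. The cholangiocyte, endothelial, macrophage, lymphocyte and MYC counts were the same adjusted over the list alone.

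edgeR called 25097 peaks for sgKmt2d without IFNG, 12487 higher and 12610 lower, or 32.2% of those tested. At least 1 on the log2 scale were 9041 (5299 higher and 3742 lower). Without both doubted libraries the call was 13900 higher and 17585 lower, and 15083 were called with a filter at the median level. Groups did not overlap at 49.5% of peaks, where chance gives 10%.

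With IFNG, the difference between sgKmt2d and vector cells was much as without it. The peaks at Dmrta2 (4.34 ± 0.14), Rp1 (4.33 ± 0.24) and Kcnd2 (3.90 ± 0.16) were again higher, as was one in Chrm3, a muscarinic receptor gene (4.26 ± 0.18). Lrrk2 was lower by −4.21 ± 0.18 (adjusted p 4.19e-13), a peak of Fhad1 by −3.60 ± 0.23 and one of Eps8, a regulator of actin, by −3.06 ± 0.16. Other called peaks of Chrm3 and Fhad1 went the other way. Over all peaks the effects of sgKmt2d with and without IFNG correlated with r = 0.832 and rho = 0.778, although peaks are not independent replicates. In both, 8230 peaks were higher where chance gives 1923, 8565 were lower where chance gives 1907, and 14 were called in opposite directions. These contrasts share no library.

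Of the gene lists with IFNG, checkpoint ligands and chemokines were lower at 16 peaks and higher at 2 (16 and 3 adjusted over the list alone). The lower peaks lay at 5 of the 13 genes with a peak, and the higher ones at 2. The 3 named Ccl2 peaks lay at −1.47 ± 0.17, −1.17 ± 0.14 and −1.04 ± 0.16, and a Cd47 peak at −1.46 ± 0.20 (fry adjusted p 0.00126, 0.349 with an estimated correlation). By camera at the preset correlation the adjusted p of this list was 0.0173, and no other list passed that test in either sgKmt2d contrast. Cd274 was higher by 0.49 ± 0.13, on chromosome 19, where the median of all peaks was 0.31. Interferon receptor and JAK genes had 14 lower and 4 higher, with the same counts adjusted over the list alone, and Ifngr2 at −1.28 ± 0.14 and −0.72 ± 0.12 (fry adjusted p 0.00215, 0.349 with an estimated correlation). Both named Jak2 peaks, at 1.97 ± 0.29 and 1.16 ± 0.21, and an Ifit2 peak at 1.69 ± 0.19 lie on chromosome 19. The response core had 24 higher and 12 lower (22 and 11 adjusted over the list alone), with Ifi47 at 1.44 ± 0.16 and Iigp1, a GTPase gene, at 1.63 ± 0.28 higher and Oas3, an antiviral synthetase gene, at −0.64 ± 0.11. Its fry adjusted p of 0.00176 became 0.414 with an estimated correlation, 0.0616 without sgKmt2d_IFNG 1, 0.0752 without sgKmt2d_IFNG 3 and 0.107 without both doubted libraries. MHC class II had 3 higher and none lower (1 and 0 adjusted over the list alone), with Ciita at 0.77 ± 0.16. Its fry adjusted p was 0.0128, 0.966 with an estimated correlation, and 0.0755, 0.147, 0.0889, 0.185 and 0.109 without vector_IFNG 2, vector_IFNG 3 and sgKmt2d_IFNG 1, 2 and 3. MHC class I had 8 higher and 1 lower (6 and 1 adjusted over the list alone), with Psmb8 at 0.75 ± 0.18 (fry adjusted p 0.102).

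The hepatocyte list had 8 higher and 5 lower with IFNG (8 and 6 adjusted over the list alone), with Foxa1 at 1.93 ± 0.24, Gpc3 at 2.89 ± 0.39 and Apob, an apolipoprotein gene, at −0.82 ± 0.15. Its fry adjusted p was 0.00655, 0.966 with an estimated correlation, and 0.214, 0.236, 0.143 and 0.198 without vector_IFNG 2, vector_IFNG 3, sgKmt2d_IFNG 1 and sgKmt2d_IFNG 3. The other lists did not pass (adjusted p 0.139 to 0.905). Higher and lower peaks were 6 and 3 for the KMT2 list (5 and 3 adjusted over the list alone), with Ash2l, a subunit of the KMT2 complexes, at 0.82 ± 0.10. They were 7 and 5 for DNA damage and repair (3 and 2), with Prkdc at 1.37 ± 0.19 and Lig4 at −1.79 ± 0.29, and 8 and 5 for p53 targets, whose median was −0.05 and mean 0.10. The cholangiocyte list had 4 and 6 (4 and 5), with peaks near Sox9 at −1.05 ± 0.13 and 1.23 ± 0.23, the mesenchymal list 19 and 22 (20 and 24), with peaks in Cdh2 at 1.90 ± 0.27 and −0.51 ± 0.11, and the endothelial list 10 and 14 (11 and 15), with Kdr at −1.10 ± 0.12. Macrophage, lymphocyte, MYC and housekeeping lists had 4 and 4, 2 and 1, 9 and 7 (6 and 6), and 0 and 5 (0 and 1), with Ccnd2 at 0.82 ± 0.11 and Actb at −0.72 ± 0.16. Counts for p53 targets, macrophages and lymphocytes were the same adjusted over the list alone.

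edgeR called 23772 peaks for sgKmt2d with IFNG, 11994 higher and 11778 lower, and 8693 changed by at least 1 on the log2 scale (5338 higher and 3355 lower). Without both doubted libraries the call was 10280 higher and 14244 lower, and 13373 were called with a filter at the median level. Scaling by library totals moved the median of all peaks in this contrast from 0.02 to 0.12 and the share of calls that were higher from 50.5% to 64.0%. Groups did not overlap at 40.2% of peaks, where chance gives 10%.

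By chromosome, the sgKmt2d contrasts differed most on chromosome 19. Its 2462 peaks, near Cd274, Jak2, Fas and Ifit2 among others, had a median of 0.33 without IFNG and 0.31 with it. The other chromosomes lay between −0.09 and 0.18 without IFNG and between −0.14 and 0.19 with it. With IFNG against DMSO the chromosome 19 median was 0.01 in each population.

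**Figure D3:**
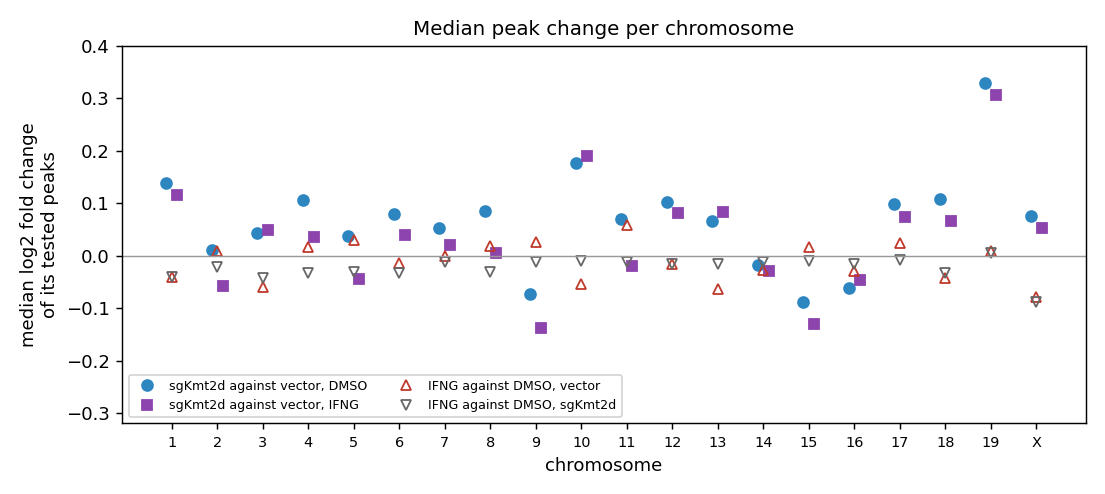
Median log2 fold change of all tested peaks on each chromosome (x axis, 1 to 19 and X; y axis, log2) in the 4 contrasts of 2 groups; points are medians over peaks. Chromosome 19 is the highest in both sgKmt2d contrasts, at 0.33 and 0.31, and lies near 0 in both IFNG contrasts.

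Called peaks lay less often at gene ends than the peaks not called. With IFNG in vector cells, 11.1% of risen and 2.79% of fallen peaks were gene-end peaks, against 16.0% of those not called (odds ratios 0.651 and 0.150, Fisher's exact test). Risen peaks turned to an odds ratio of 2.22 without vector_IFNG 3, and fallen peaks lay at 0.246 without both doubted libraries. In sgKmt2d cells the shares with IFNG were 6.99% and 3.23% against 15.9% (odds ratios 0.396 and 0.176). For sgKmt2d without IFNG they were 15.5% of higher and 4.58% of lower peaks against 18.2% (odds ratios 0.825 and 0.216). The ratio for lower peaks was 0.341 without vector_IFNG 2 and 0.383 without both doubted libraries, and that for higher peaks became 1.42 with the trend on the level removed, 0.957 without vector_IFNG 2 and 0.973 without both doubted libraries. For sgKmt2d with IFNG they were 10.4% and 8.30% against 18.3% (odds ratios 0.516 and 0.403), the first 0.835 without vector_IFNG 2 and 1.00 without both doubted libraries, the second 0.957 without vector_IFNG 3.

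The peak lists of single libraries held 57696 ± 489 peaks in vector_DMSO (mean ± SD, n = 3), 63150 ± 3385 in vector_IFNG, 58027 ± 1409 in sgKmt2d_DMSO and 57646 ± 6170 in sgKmt2d_IFNG. The covered length was 36.0, 37.2, 35.7 and 36.0 Mb. The difference of IFNG minus DMSO within transduction was 2536 peaks (exact permutation p 0.295) and that of sgKmt2d minus vector within treatment −2587 (exact permutation p 0.320). The first was 4174 without sgKmt2d_IFNG 3 (exact permutation p 0.015) and 1112 without sgKmt2d_IFNG 2. Regions of vector_DMSO were shared with vector_IFNG in 91.7% of cases (50587 of 55144) and with sgKmt2d_DMSO in 83.4% (45997 of 55144). Regions of sgKmt2d_DMSO were shared with sgKmt2d_IFNG in 89.1% (48772 of 54762), and those of vector_IFNG with sgKmt2d_IFNG in 81.0% (47350 of 58445).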

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

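Of the tests in this part, those on copies of chromosome 19, on vector_IFNG 2 as the source of the fallen peaks and on other splits of the libraries were chosen after the result was seen.

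With p-values adjusted over the list alone, the IFNG effect differed between the populations at 8 peaks of the response core, 3 higher and 5 lower in sgKmt2d cells, and at 3 of the cell cycle list, 1 higher and 2 lower. None passed over all peaks. The 7 below are those that the naming rule, at most 4 per list, took. A peak 14842 bp from Gbp4, a guanylate-binding protein gene (chromosome 5, 105153944 to 105154912), had 0.48 in vector cells (adjusted p 0.0992) and rose by 1.64 in sgKmt2d cells. The difference was 1.16 ± 0.24 (adjusted p 0.0116 over the list and 0.201 over all peaks, 0.0133 to 0.477 over the settings). An Ifi47 peak (chromosome 11, 49086724 to 49087400) rose less in sgKmt2d cells, 2.06 against 3.22, a difference of −1.16 ± 0.28 (0.0233 and 0.257, 0.0488 to 0.587). A peak 6020 bp from Socs1 had 0.46 against 1.22, a difference of −0.76 ± 0.19 (0.0233 and 0.276, 0.0774 to 0.544). Another Ifi47 peak, 677 bp from the gene, had 2.62 against 0.25, a difference of 2.37 ± 0.59 (0.0233 and 0.276, 0.104 to 0.568). An adjusted p was available for this peak in 23 settings and for the Ccne1 peak below in 24, against 25 for the rest. For the cell cycle list, the differences were −1.02 ± 0.26 in Ccnd2 (0.0302 and 0.276, 0.0816 to 0.532), −1.15 ± 0.30 near Ccne1 (0.0302 and 0.30, 0.111 to 0.625) and 0.74 ± 0.21 near Ccnd1 (0.0495 and 0.363, 0.103 to 0.627). Over all peaks, Gbp4 and the first Ifi47 peak passed only with the DESeq2 Wald test, and the other 5 in no setting.

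For the interaction the response core had a mixed fry adjusted p of 0.0163, with peaks on both sides, and its directional test did not pass (adjusted p 0.690). No tested peak lay on chromosome Y, so its peaks enter through the peak lists of single libraries alone. There, sgKmt2d libraries had 16.5 more chromosome Y peaks than vector libraries within treatment (exact stratified permutation p 0.020, 0.480 adjusted over 24 tests). The means were 107 ± 11.3 in sgKmt2d_DMSO, 83.3 ± 6.03 in vector_DMSO, 91.7 ± 9.50 in sgKmt2d_IFNG and 82.3 ± 9.87 in vector_IFNG (SD, n = 3). No explanation was tested for either.

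Chromosome 19 peaks were higher in sgKmt2d cells, by a median of 0.33 without IFNG and 0.31 with it, across Cd274, Jak2, Fas and Ifit2. A trend of the fold on the mean level is argued against, since the median was still 0.32 after its removal. The error of that median, 0.01, came from redrawing peaks, which are not independent replicates, and not from the spread between libraries. The mix of peak classes and levels is argued against too, since matched draws from other chromosomes reached a median of at most 0.0852. All 7 windows of 10 Mb had medians between 0.26 and 0.36, which is consistent with more copies of the chromosome in the sgKmt2d cells, a fold of 1.26 over the population. A rise of its chromatin activity as a whole would look alike, so the windows cannot tell it from more copies. No other biological explanation was tested. Whether it came with the guide or with the cells that were selected cannot be read from 2 populations.

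Library vector_IFNG 2 stood apart from its group. Each library was compared with the mean of the other libraries of its group. For vector_IFNG 2, the deviation at gene-end peaks exceeded that at intergenic peaks by 0.40 on the log2 scale. Libraries of the other groups lay between −0.14 and 0.09. Those of vector_IFNG 1 and 3, −0.16 and −0.26, were taken against a mean that includes vector_IFNG 2. A library with more of its signal at gene ends may account for how vector_IFNG 2 stood apart. Depth is argued against, because after thinning it to the others' total the gap in correlation was 0.0193. A stronger interferon response is argued against by an excess of −0.0174 (log2) over the response core. What made the signal differ stays open, since the labels give no batch.

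Fewer peaks fell with IFNG in sgKmt2d cells, 496 against 1612, a ratio of 3.25. Without vector_IFNG 2 the counts were 1284 and 975, a ratio of 0.759, so that library could account for the difference, but it is not the only choice that removes or shrinks it. A fit to the 6 libraries of each contrast, with none left out, gave 977 and 660, and leaving out vector_DMSO 2 gave 405 and 593, while leaving out vector_IFNG 3 widened it to 576 and 2946. For a smaller fall of the same peaks in sgKmt2d cells, held-out libraries gave ratios of vector to sgKmt2d medians of 1.56, 2.14 and 1.25, and for peaks chosen in sgKmt2d cells ratios of sgKmt2d to vector medians of 1.35, 1.28 and 0.785, so this explanation cannot be told apart from equal falls. The difference between the populations in the IFNG effect, tested directly, called 0 peaks in edgeR (5942 at an unadjusted p below 0.05, 106 by the DESeq2 Wald test and 0 by limma-voom).

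The splits of the 6 libraries of a contrast of 2 groups were too few, 10 each, for a share below 0.05, and 1 in each contrast, the real one, called as many. The real split called 4253 peaks for IFNG in vector cells and the highest other split 1. For IFNG in sgKmt2d cells these were 2815 and 0, for sgKmt2d without IFNG 25097 and 0, and with IFNG 23772 and 0. For the interaction, 40 groupings of the 12 libraries were fitted, the real one and random ones, and the real one called 0. All 40 then call as many by construction, so the comparison decides nothing about the interaction. The highest other split called 273, which points to a structure of the samples. It set the 3 vector_DMSO libraries against the 3 sgKmt2d_IFNG libraries, and no further test was made of it.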

How the results depend on the processing

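The settings without the 10 highest peaks, with the trend on the level removed, without both doubted libraries (vector_IFNG 2 and sgKmt2d_IFNG 3) and with gene-end peaks alone were chosen after seeing the data, as was every setting of a gene list or of the shares at gene ends other than estimated correlation and the replicate block. The 4 interferon lists kept their rise with IFNG in both populations in all 19 settings, and the sharing of peaks between groups stayed within 1.5 times. Of the tests of 290 pairs of a named peak and a contrast over the settings, 6961 kept direction and side of the threshold. Another 218 fell short of it (45 pairs), 2 newly passed and 0 turned. Apart from Kmt2d and the interaction, only pairs called in the main fit were followed, so a turn was unlikely from the start. The replicate number as a block gave 3701, 2527, 24250, 22975 and 0 peaks for the 5 contrasts. No pairing by number was visible, since correlations of libraries with the same number lay between −0.17 and 0.17 and only 3 of 12 correlated best with their own. Whether libraries of the same number were prepared together is not given in the sources used here. Small changes can be missed, since 17.9% to 29.9% of simulated 1.5-fold changes were recovered in contrasts of 2 groups. Few peaks changed in those simulations, so the shares may be too low for contrasts with many calls. The planned GC correction and motif settings were not run, since no genome sequence was used here. Promoter classes were not run, since the gene table has no transcription starts. Where no reason is given, the cause was not tested.

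Counts changed with the filter at the median level, which tests fewer peaks, to 2732 for IFNG in vector cells, 1663 in sgKmt2d cells, 15083 for sgKmt2d without IFNG and 13373 with it. With a fold limit of 1 on the log2 scale, stricter by construction, they were 1596, 1246, 9041 and 8693. A fit to 6 libraries alone gave 2480 for IFNG in vector cells, and leaving out both doubted libraries gave 4803 for IFNG in sgKmt2d cells. The interaction called 1 with library totals, 1 with the filter at the median level, 1 without the 10 highest peaks, each a peak at Taf1b, and 2 with the trend removed, at Taf1b and Tspan9, named after their values were seen. It called 84 without both doubted libraries and 106 by the DESeq2 Wald test. Leaving out 1 library gave 2289 to 6857 for IFNG in vector cells, 1731 to 4943 in sgKmt2d cells and 0 to 11 for the interaction. The difference in peaks per library for sgKmt2d minus vector was −3393 at a −log10 q of at least 5 and −3285 at 10. Their exact permutation p was 0.030 and 0.020, not adjusted for the number of tests. With no q limit the exact permutation p was 0.320, or 0.738 adjusted over 24 tests. The difference for IFNG minus DMSO lay between 1112 and 4174 on leaving out 1 library.

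The odds ratio at gene ends for peaks higher in sgKmt2d cells without IFNG was 0.965 with library totals, 0.970 in a fit to 6 libraries, 0.973 without both doubted libraries and 1.42, turned, with the trend removed. With IFNG it was 1.00, turned, without both doubted libraries. On leaving out 1 library it was 0.480 to 2.22 for risen peaks with IFNG in vector cells, 0.702 to 0.957 for higher peaks without IFNG and 0.330 to 0.957 for lower peaks with IFNG. The correlation of the IFNG effects was 0.616 at levels above the median, 0.282 at peaks called in neither, 0.489 without both doubted libraries and 0.467 to 0.517 on leaving out 1 library.

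The gene lists of the sgKmt2d contrasts depended on the setting in many cases, given here as adjusted p. With an estimated correlation, without IFNG, they were 0.949 for MHC class I, p53 targets and MYC, 0.853 for MHC class II and hepatocyte identity, 0.413 for the response core and checkpoint ligands and 0.845 for receptor and JAK genes. With IFNG they were 0.966 for MHC class II and hepatocyte identity, 0.414 for the core and 0.349 for checkpoint ligands and receptor and JAK genes. Without IFNG, MHC class I had 0.102 with the block, 0.0896 without both doubted libraries, 0.0780 with DESeq2 size factors, 0.0868 with library totals and 0.128 with 10 Mb offsets. MHC class II had 0.312 with 10 Mb offsets and 0.205 at gene ends. Receptor and JAK genes had 0.290 with library totals and 0.722, turned, at gene ends. The p53 targets had 0.834, turned, without both doubted libraries, 0.427 with DESeq2 size factors, 0.119 with library totals, 0.252, turned, with 10 Mb offsets and 0.339 at gene ends, and hepatocyte identity had 0.620 at gene ends. With IFNG, MHC class II had 0.122 without both doubted libraries, 0.0520 with the trend removed, 0.288 with 10 Mb offsets and 0.983, turned, at gene ends. The core had 0.107 without both doubted libraries. Receptor and JAK genes had 0.346 with library totals and 0.473 at gene ends. Hepatocyte identity had 0.665 without both doubted libraries, 0.0611 with the trend removed, 0.0706 with 10 Mb offsets and 0.231, turned, at gene ends. On leaving out 1 library, without IFNG, MHC class I had 0.0422 to 0.166, receptor and JAK genes 0.00145 to 0.0594, p53 targets 0.0105 to 0.721 and MYC 0.00565 to 0.0753. With IFNG, MHC class II had 0.00337 to 0.185, the core 0.00136 to 0.0752 and hepatocyte identity 0.00547 to 0.236.

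Lists that had not passed did so in the same direction in 28 settings of 12 lists and contrasts. DNA damage and repair, lower without IFNG, passed in 7 of 19 settings, at 0.00819 in the lowest, without vector_IFNG 2. Others passed to the other side, 7 in all. At gene ends these were the cholangiocyte and mesenchymal lists without IFNG, at 0.000396 each, and the cholangiocyte list with IFNG, at 0.00424. With IFNG, library totals gave 0.0266 for DNA damage and 0.0255 for housekeeping, 10 Mb offsets 0.0126 for p53 targets and leaving out both doubted libraries 0.00855 for the mesenchymal list.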

Other observations

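All tests in this part were chosen after the values were seen, and so were the genes named. In some genes nearly every peak differed between sgKmt2d and vector cells to the same side, with and without IFNG. Of 3455 genes with at least 6 peaks, 17 had at least 80% of their peaks higher in both sgKmt2d contrasts and 12 had at least 80% lower, where the highest of 1000 shuffles of the peaks gave 1 and 2. The higher genes include Esrrg, a nuclear receptor gene (11 of 12 peaks, medians 2.01 without and 2.45 with IFNG), Sema6a, a semaphorin gene (10 of 11, 2.44 and 2.83), and Clstn2, a calsyntenin gene (6 of 6, 2.42 and 2.79). All 6 peaks of Mef2c, a transcription factor of muscle and neurons, were higher (1.78 and 2.10), as were all 6 of Hoxa3, a homeobox gene (1.47 and 1.42), and 13 of 16 in Celsr1, a cadherin of planar polarity (1.38 and 1.21).

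On the lower side were Eps8 (10 of 10 peaks, −1.74 and −2.11), Enox1 (9 of 10, −1.87 and −1.77), the adhesion gene Cadm1 (12 of 15, −1.62 and −1.52), Lrrk2 (5 of 6, −2.30 and −2.37) and Xdh, which encodes xanthine dehydrogenase (6 of 7, −1.77 and −1.60). Neighbouring peaks are not independent, and shuffles break up any regional difference, so the shuffled counts are a low bar.

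Of 264 windows of 10 Mb, 20 had a median above 0.25 in both sgKmt2d contrasts. Chromosome 19 held 7 of them and chromosomes 1, 10, 3, 5, 12 and 14 the rest. In 2 windows, both on chromosome 9 within its first 20 Mb, the median was below −0.25 in both. Weak peaks lay higher in sgKmt2d cells than strong ones, with a median of 0.30 in the lowest 10% of levels and 0.01 in the highest 10% without IFNG, and 0.25 and −0.10 with it. Library vector_IFNG 2 had 13 peaks on the mitochondrial chromosome and a median peak width of 440 bp.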
